A study of Mus musculus with 6 samples.

How the data were processed

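RNA was measured in 6 samples of primary mouse synovial fibroblasts, 3 treated with DMSO and 3 with compound 33, and each sample gave 1 library. Per the labels' protocols, the cells came from ankle joints of hTNFtg mice and were grown for 3 passages. They then received 10 µM compound 33 or DMSO for 48 h, RNA with an integrity number above 7 was used, and libraries were made with the QuantSeq 3′ mRNA kit and sequenced on an Ion Proton instrument. This kit primes on the poly(A) tail and yields reads near the 3′ end of each transcript, so a gene's count follows the number of its transcripts and no correction for gene length was applied.

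The submitters' processing notes name FastQC 0.11.9, HISAT2 2.2.1, featureCounts 2.0.3, DESeq2 without a version, and the genome build mm10. The gene annotation, the strand setting of the counting and the treatment of reads that match several genes are not given in the sources used here. The authors deposited a table of whole-number read counts per gene symbol for the 6 libraries, with no normalization. A separate table that the authors deposited holds their comparison of compound 33 with DMSO, in which the mean normalized count is a signal averaged over all libraries, the fold change and its standard error are on the log2 scale, and the Wald statistic is a score. The p-value and the adjusted p-value complete the deposited comparison. Every column of per-sample values in the count table was used.

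The count table lists 21033 gene symbols, of which 6181 had no read in any library. Of these symbols, 99.0% matched the GENCODE M21 annotation of the same build, and 99.5% of the matched ones were protein coding. The table holds 0 genes of the mitochondrial genome, so the share of mitochondrial reads could not be used as a sign of RNA quality. Coordinates are gene bodies from that annotation on mm10, counted from 1, and were given only for symbols that matched a single gene. Without a stated strand setting, reads of genes whose exons overlap on opposite strands cannot be told apart. Among the named genes that were looked up there, this concerns Actn1, Ahr, Atf5, Bnip3, Cars, Cebpa, Chsy1, Has2, Hif1a, Irf7, Mmp11, Ndrg1, Ost4, Pdgfra, Prelp, Prg4, Psmb8, Tgfb3, Tiparp, Tnfaip2, Tpm4, Vcam1 and Vcl. Exons of Actg1, Ctsd, Gm42674, Hif1a and Pdgfra overlap another annotated gene on the same strand.

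Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with its default minimum count of 10, which left 10124 genes holding over 99.4% of the reads of each library. Libraries were scaled by the TMM method, and levels are given as counts per 1000000 reads (CPM) of the scaled library size, as mean ± SD over 3 libraries. Differences between groups were tested with edgeR's quasi-likelihood F test with robust estimation, fitted to all 6 libraries with group as the only term, two-sided, and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The standard error of a log2 fold change was the unshrunk log2 fold change divided by the square root of F, and 95% intervals used the degrees of freedom of that test. The typical coefficient of variation between libraries of a group, beyond counting noise, was 23.6%. The labels give no batch or sequencing date.

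Before the data were examined, 31 gene lists were written down, covering stress responses, inflammation, matrix, contractile genes, metabolism, states of synovial fibroblasts and markers of other cell types that a joint culture could hold. The 23 lists with at least 5 tested members were compared with all other tested genes by camera, part of limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 23 lists. Each list was also tested with a correlation estimated from the data and with fry, whose p tests whether the members move one way on balance without comparing them with other genes. For each list the members that passed were counted both over all genes tested and adjusted over the list alone.

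The genes named in the text were set by a rule written before the data were examined. It took Hyou1, up to 12 named genes in each direction with the largest fold change among those that passed with groups that did not overlap and a mean of at least 20 CPM in the higher group, and up to 4 members per list that passed or otherwise the 2 most abundant members. It also took Tnf, the markers Thy1, Pdpn, Prg4, Pdgfra, Vim and Cdh11, and the 5 most abundant genes, and allowed members to be left out for length. Because 3 genes passed, further genes are named after their values were seen. These are the genes that passed in the authors' deposited table, list members that passed with adjustment over the list alone, and other members given as examples of a list.

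The alternatives tried were other library scalings, no or a stricter low-count filter, edgeR without robust estimation, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, other thresholds, and other settings of the list test. The edgeR and DESeq2 steps were first tested on simulated counts drawn from the means and library sizes of the 10124 genes, with 100 genes changed 2-fold and 100 changed 4-fold in each of 5 draws. With 3 libraries against 3, edgeR recovered 30.8% of the 2-fold and 91.2% of the 4-fold changes, and 6.96% of its calls were false. DESeq2 recovered 34.6% and 89.2%, with 8.65% of calls false. Because the adjusted p depends on how many genes change, these shares hold for that number and may overstate recovery where fewer change. In the real comparison Il6 and Rsad2 had log2 fold changes of -2.50 and 3.31 and did not pass (edgeR adjusted p = 0.212 and 0.211). A list shifted by 0.8 on the log2 scale passed in 5 of 5 draws, and 2 unshifted lists passed over all draws. Genes were drawn independently of each other, whereas the correlation estimated for the interferon list was 0.35. The draws therefore cannot show how often camera passes lists whose members vary together.

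Library totals ran from 1594052 to 2897207 reads. A single read was worth 0.348 to 0.611 CPM, and the level that 0 reads allow, taken as 3 reads, lay between 1.04 and 1.83 CPM per library. These limits cover counting error only, since reads without molecular identifiers are not independent molecules.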

Results

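Transcript levels were measured in synovial fibroblasts, the mesenchymal cells that line the joint cavity and fill the tissue beneath it. The cells came from ankle joints of hTNFtg mice, which carry a human TNF transgene and develop chronic arthritis, and were kept in culture for 3 passages. They were exposed for 48 h to 10 µM compound 33 or to DMSO, the vehicle, with 3 libraries per group. The DMSO libraries held 1913730, 2179455 and 2897207 reads, and the compound 33 libraries held 1594052, 2384850 and 2073016 reads. Pearson's r of log2 CPM across genes lay between 0.920 and 0.963 for libraries of the same group and between 0.922 and 0.965 for libraries of different groups, a correlation across genes, which are not independent replicates. Each pair of libraries in a group differed by more than sampling noise, with a chi-square per degree of freedom of 4.56 to 18.9. This measure covers counting error only and cannot tell separate cultures from technical repeats. All libraries were counted as separate samples. The labels do not say that the replicates of a group are separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

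The comparison of compound 33 with DMSO asks which transcripts of activated fibroblasts change under a molecule that the series title links to Hyou1, a chaperone of the endoplasmic reticulum. Ahrr, a target gene and repressor of the aryl hydrocarbon receptor, rose 14.6-fold, from 2.21 ± 1.65 CPM with DMSO to 35.4 ± 4.40 CPM with compound 33 (mean ± SD, n = 3 per group). Sfrp1, a secreted antagonist of Wnt signalling, fell 3.62-fold, from 390.4 ± 56.4 to 108 ± 17.1 CPM. Ppbp, the chemokine CXCL7, fell 5.57-fold, from 90.1 ± 27.7 to 16.0 ± 6.57 CPM. For each of these 3 genes, all libraries of one group lay beyond all libraries of the other. Hyou1 itself stood at 86.7 ± 34.1 CPM with DMSO and 94.9 ± 3.67 CPM with compound 33.

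These were the only genes of the 10124 tested that passed edgeR's quasi-likelihood test, 1 upward and 2 downward. The log2 fold change was 3.86 (SE 0.42, adjusted p = 0.00412) for Ahrr, -1.86 (SE 0.22, adjusted p = 0.00553) for Sfrp1 and -2.48 (SE 0.34, adjusted p = 0.0168) for Ppbp. For Hyou1 it was 0.14 (95% interval -0.44 to 0.72, adjusted p = 0.956), and the estimate was -0.09 without DMSO replicate 2 and 0.47 without DMSO replicate 1. Before adjustment 696 genes lay under 0.05, 369 of them higher and 327 lower with compound 33, and 1353 genes (13.4%) had groups that did not overlap, where chance gives 10%. On mm10, Ahrr lies on chromosome 13 at 74211118 to 74292331 on the minus strand, and Sfrp1 on chromosome 8 at 23411502 to 23449632 on the plus strand. Ppbp lies on chromosome 5 at 90768518 to 90770063 on the plus strand, and Hyou1 on chromosome 9 at 44379490 to 44392369 on the plus strand. All of them are protein coding, and their exons overlap no other annotated gene. Ahrr, which had 1, 5 and 11 reads in the DMSO libraries, passed whichever library was left out, with a log2 fold change of 4.55 without DMSO replicate 3 and 3.48 without DMSO replicate 1. In contrast, Sfrp1 did not pass without DMSO replicate 3 (adjusted p = 0.0781) or without compound 33 replicate 1 (adjusted p = 0.0604), both at the edgeR test. Ppbp passed only when DMSO replicate 1 was the library left out, its adjusted p reached 0.213 without DMSO replicate 3, and in limma-voom it was 0.0560. In all, 7 genes passed without DMSO replicate 1, 3 without DMSO replicate 2 or compound 33 replicate 2, 2 without compound 33 replicate 3, and Ahrr alone without DMSO replicate 3 or compound 33 replicate 1.

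**Figure D1:**
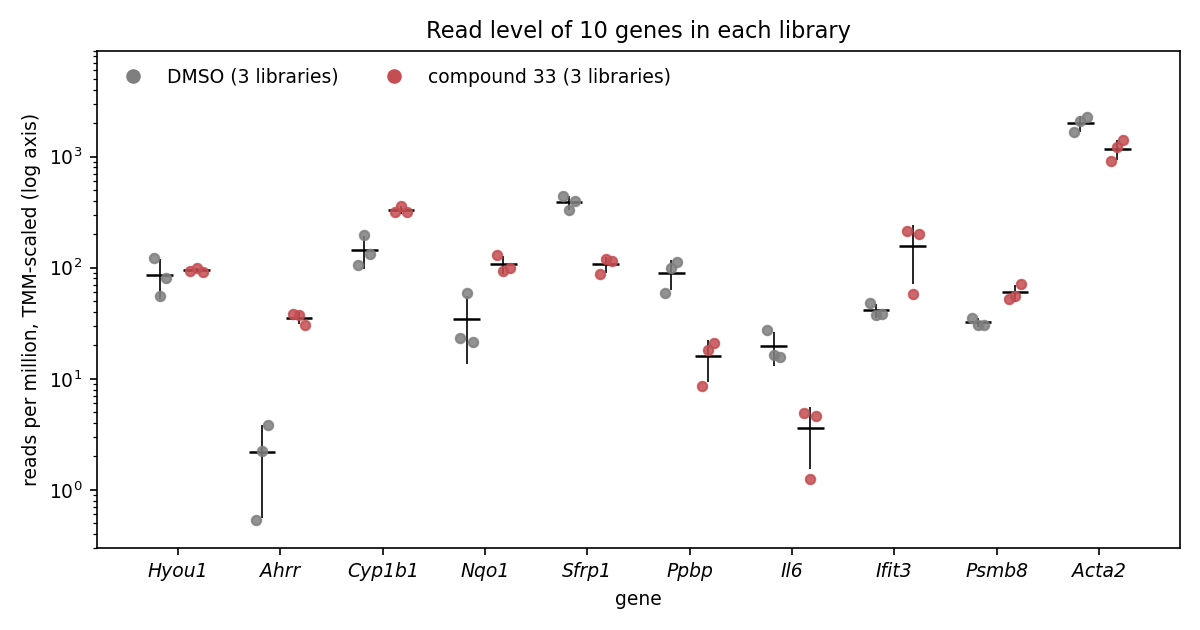
Level of 10 genes in CPM for each library on a log axis, with points for the 3 DMSO (grey) and 3 compound 33 (red) libraries, horizontal bars for the mean and vertical bars for the SD. Ahrr stands at 2.21 CPM on average with DMSO and at 35.4 CPM with compound 33, the groups of Hyou1 overlap, and only Ahrr, Sfrp1 and Ppbp passed the edgeR test over all genes.

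The authors' deposited table holds 18 genes with an adjusted p under 0.05, 9 higher and 9 lower with compound 33. Upward in the authors' deposited table were Ahrr, Cyp1b1, Nqo1, Ifit3, Rsad2, Ifi207, Klf9, Car6 and Timp2. Downward in the authors' deposited table were Sfrp1, Ppbp, Il6, Cxcl3, Actg1, Csrp2, Plat, Ost4 and Chsy1. A DESeq2 fit of the deposited counts gave the same 18 genes as the authors' deposited table, with every log2 fold change within 0.01 of it. All 18 had the same sign and an unadjusted p under 0.05 in edgeR, and 3 of them passed there, the others reaching an adjusted p of up to 0.368. In the authors' deposited table, Il6 has a log2 fold change of -2.51 (SE 0.55, adjusted p = 0.00618), Cyp1b1 1.19 (SE 0.26, adjusted p = 0.00540) and Ifit3 1.93 (SE 0.38, adjusted p = 0.000807). Without a low-count filter edgeR passed 21 genes, 14 of them among the 18 of the authors' deposited table. At an adjusted p under 0.01, the authors' deposited table holds 14 genes and edgeR 2, both shared.

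Genes of the aryl hydrocarbon receptor, a ligand-activated transcription factor that controls xenobiotic metabolism, were shifted upward as a list. Besides targets of the receptor, this list holds Ahr itself and broader xenobiotic genes such as Por, Ephx1 and the transporters Abcb1a and Abcb1b. Of 11 tested members 9 had a positive log2 fold change, with a median of 0.45 (camera adjusted p = 4.37e-11, adjusted p = 0.119 with an estimated correlation). Over all genes Ahrr was the only member that passed in edgeR or limma-voom, while DESeq2 passed 3, Ahrr, Cyp1b1 and Nqo1. Without a low-count filter Cyp1b1 (adjusted p = 0.0113) and Nqo1 (0.0267) passed in edgeR too, as did Nqo1 without DMSO replicate 2 (0.00868). Adjusted over the list alone, 5 members were higher and 0 lower in edgeR, namely Ahrr, Cyp1b1, Nqo1, Tiparp and Aldh3a1. Cyp1b1, a cytochrome P450 of chromosome 17 (79701537 to 79715061), stood at 146 ± 47.5 and 331 ± 25.3 CPM, a log2 fold change of 1.18. Nqo1, a quinone reductase of chromosome 8 (107388225 to 107403206), stood at 34.5 ± 20.9 and 107 ± 20.1 CPM, a log2 fold change of 1.64. Tiparp, an ADP-ribosyltransferase that represses the receptor, stood at 19.9 ± 13.0 and 51.2 ± 21.5 CPM. Aldh3a1, an aldehyde dehydrogenase, stood at 2.65 ± 0.839 and 7.48 ± 3.40 CPM. Cyp1a1 had 5 reads in compound 33 replicate 2 and 0 in the other libraries. The receptor itself, Ahr, stood at 11.3 ± 2.9 and 7.14 ± 1.6 CPM and did not pass (log2 fold change -0.66, adjusted p = 0.794).

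Interferon-stimulated genes formed the list with the largest median shift. Of 32 tested members 30 had a positive log2 fold change, with a median of 0.82 (camera adjusted p = 9.22e-19, adjusted p = 0.147 with an estimated correlation). Adjusted over the list alone, 14 members were higher and 0 lower. Over all genes edgeR passed 0 members, where 16 lay under an unadjusted 0.05, DESeq2 passed 2, Ifit3 and Rsad2, and limma-voom 0. In edgeR these also passed with the replicate block (adjusted p = 0.0478 and 0.0277), Rsad2 without a low-count filter (0.00143) and Ifit3 without compound 33 replicate 2 (0.00574). Ifit3, an antiviral protein, stood at 41.5 ± 5.87 CPM with DMSO and 158 ± 86.7 CPM with compound 33, and Rsad2, or viperin, at 1.14 ± 0.609 and 12.1 ± 6.58 CPM. Psmb8, an immunoproteasome subunit, stood at 32.1 ± 2.95 and 59.9 ± 10.7 CPM, and the transcription factor Irf7 at 5.18 ± 0.947 and 14.6 ± 4.55 CPM. The mean log2 CPM of the list was 4.87, 4.75 and 4.76 in the DMSO libraries and 6.0, 5.04 and 5.60 in the compound 33 libraries. Without compound 33 replicate 1 the list's median was 0.52 (camera adjusted p = 5.38e-09). Ifit3 is nearly identical to its neighbour Ifit3b, and Ifi207 belongs to a family of close relatives, so their counts are uncertain. Exons of Irf7 overlap those of Phrf1 on the opposite strand, and the strand setting of the counting is not given in the sources used here.

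Among the lists of cellular stress, 3 passed upward. Those of the endoplasmic reticulum, cytosolic heat shock (camera adjusted p = 0.80) and p53 signalling (camera adjusted p = 0.665) did not pass. Targets of the integrated stress response, which ATF4 and CHOP control, were shifted upward, with 27 of 33 tested members positive and a median log2 fold change of 0.17 (camera adjusted p = 4.47e-05, adjusted p = 0.119 with an estimated correlation). No member passed by itself, neither over all genes nor adjusted over the list alone, with 6 under an unadjusted 0.05 in edgeR and 0 passing in DESeq2 or limma-voom. Its larger log2 fold changes belonged to the cystine transporter Slc7a11 (1.11, SE 0.36), the secreted glycoprotein Stc2 (1.03, SE 0.43), the tRNA synthetases Wars (0.92, SE 0.25) and Cars (0.67, SE 0.22), and Ddit3 (0.71, SE 0.25), which encodes CHOP. The 2 most abundant members were Atf5 (0.52, SE 0.25) and Atf4 itself (0.26, SE 0.24). Values were small for Asns (0.17), Trib3 (0.14), Psat1 (0.08), Shmt2 (0.03), Sesn2 (-0.03) and Ppp1r15a (-0.17). Chaperones and folding enzymes of the endoplasmic reticulum, the group to which Hyou1 belongs, had a median of 0.03 over 33 tested members (camera adjusted p = 0.961). Hspa5, or BiP, the main chaperone of that compartment, stood at 3315 ± 600.2 and 4054 ± 221 CPM (log2 fold change 0.29, adjusted p = 0.886). NRF2 antioxidant genes passed upward (camera adjusted p = 0.00832, adjusted p = 0.124 with an estimated correlation) with a median of only 0.01 over 29 members, 17 of them positive. Nqo1 and the glutathione transferase Gsta3 (2.48 ± 0.797 and 9.29 ± 4.01 CPM) passed when adjusted over that list alone, and the list's median ran from -0.03 without DMSO replicate 3 to 0.26 without DMSO replicate 2, with each library left out in turn. Lysosomal and autophagy genes passed upward with a median of 0.12 over 38 members (camera adjusted p = 0.00915, adjusted p = 0.578 with an estimated correlation). No member of it passed over all genes in edgeR, DESeq2 or limma-voom or over the list alone, and 5 lay under an unadjusted 0.05 in edgeR, all higher, among them the sialidase Neu1 (log2 fold change 0.73, SE 0.23) and the protease Ctsd (0.58, SE 0.26). This list did not pass without DMSO replicate 2 (adjusted p = 0.371) or without compound 33 replicate 3 (adjusted p = 0.313), and its median was 0.20 without DMSO replicate 1.

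Inflammatory mediators of activated fibroblasts were shifted downward as a list. Of 29 tested members 18 had a negative log2 fold change, with a median of -0.29 (camera adjusted p = 0.00321, adjusted p = 0.119 with an estimated correlation). Adjusted over the list alone, 4 members were lower and 1 was higher with compound 33. Il6, a cytokine gene of chromosome 5 (30013114 to 30019981), stood at 19.8 ± 6.72 CPM with DMSO and 3.59 ± 2.04 CPM with compound 33, a log2 fold change of -2.50. The lower members also included the hyaluronan synthase Has2 (28.4 ± 4.06 and 11.6 ± 1.74 CPM), the prostaglandin synthase Ptgs2 (214 ± 37.5 and 117 ± 26.4 CPM) and the chemokine Cxcl14 (2021 ± 941 and 847 ± 398 CPM). The adhesion molecule Vcam1 went the other way, at 451 ± 100.4 and 787 ± 125 CPM. Over all genes edgeR passed 0 members, with 8 lower and 1 higher under an unadjusted 0.05, where DESeq2 passed 1, Il6, and limma-voom 0. In edgeR Il6 also passed with the replicate block (adjusted p = 0.0478) and without a low-count filter (0.00143). Ccl2 (log2 fold change -0.56, adjusted p = 0.719) and the acute-phase gene Saa3 (-0.66, adjusted p = 0.714) did not pass. Without DMSO replicate 2 the median of the list was -0.07 (camera adjusted p = 0.0115). Feedback targets of NF-κB, the transcription factor downstream of TNF, did not pass, with a median of 0.16 over 26 members (camera adjusted p = 0.0958). They passed without compound 33 replicate 3 (adjusted p = 0.0455) and with members under 10 CPM left out (adjusted p = 0.0454), and Tnfaip2 had the value of 1047 ± 210.5 against 1955 ± 876 CPM. Mouse Tnf had 2 reads in DMSO replicate 1, 1 in compound 33 replicate 2 and 0 elsewhere, and the human transgene was not analysed here.

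Contractile and TGF-β-responsive genes were shifted downward as a list, with 26 of 34 tested members negative and a median log2 fold change of -0.37 (camera adjusted p = 2.94e-06, adjusted p = 0.200 with an estimated correlation). Adjusted over the list alone, 6 members were lower and 1 was higher, where edgeR over all genes passed 0, with 10 lower and 1 higher under an unadjusted 0.05, and DESeq2 and limma-voom passed 0. Acta2, smooth muscle actin and a marker of myofibroblasts, stood at 2003 ± 317 CPM with DMSO and 1179 ± 245 CPM with compound 33. Cnn1, or calponin, stood at 43.1 ± 8.61 and 20.1 ± 9.26 CPM, the tropomyosin Tpm4 at 1156 ± 186 and 644 ± 194 CPM, and the adhesion protein Vcl, or vinculin, at 238 ± 18.9 and 143 ± 13.2 CPM. The other lower members were Tgfb3 and Tgfbi, and the higher one was the integrin Itgb5 (313 ± 94.2 and 624 ± 86.0 CPM). The 2 most abundant members had small log2 fold changes, Ctgf 0.21 (SE 0.36) and Actn1 -0.03 (SE 0.22). Estimates were also small for Cyr61 (0.04), Ltbp2 (0.01), Tgfb1 (-0.01) and Smad7 (-0.10), so the shift was not shared by every member. Without compound 33 replicate 1 the median of the list was -0.17 (camera adjusted p = 0.00514). Outside the list, Actg1, a cytoplasmic actin, has a log2 fold change of -0.95 (SE 0.21) in the authors' deposited table with an adjusted p of 0.00618, and in edgeR it did not pass (adjusted p = 0.266).

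Matrix genes and the markers of the fibroblasts below the lining were shifted downward by smaller amounts. The matrix list had 33 of 53 tested members negative and a median of -0.17 (camera adjusted p = 0.0164, adjusted p = 0.377 with an estimated correlation). No member of it passed over all genes in edgeR, DESeq2 or limma-voom or over the list alone, and 10 lay under an unadjusted 0.05 in edgeR, 9 lower and 1, Prelp, higher. Among the lower ones, lumican (Lum) had a log2 fold change of -0.68 (SE 0.23), versican (Vcan) -0.60 (SE 0.21), periostin (Postn) -0.69 (SE 0.25) and Col12a1 -0.64 (SE 0.24). The sublining list, which holds Sfrp1, had 11 of 16 tested members negative and a median of -0.22 (camera adjusted p = 0.0360, adjusted p = 0.221 with an estimated correlation), and its marker Thy1 stood at 765 ± 166 and 486 ± 52.0 CPM (adjusted p = 0.605). Under an unadjusted 0.05, 2 of its members were lower, Sfrp1 and Thy1, and 2 higher, Pdgfrb (log2 fold change 0.62, SE 0.23) and Ly6a (0.57, SE 0.25). Neither list passed without DMSO replicate 2 (adjusted p = 0.137 for matrix and 0.319 for sublining), without DMSO replicate 3 (0.072 for both) and without compound 33 replicate 1 (0.148 and 0.329), and the matrix median was -0.31 without DMSO replicate 1. The sublining list also did not pass without a low-count filter (0.160), with a stricter one (0.115), with members under 10 CPM left out (0.0905) or in limma-voom (0.138). Enzymes of matrix degradation and their inhibitors did not pass as a list (32 tested members, camera adjusted p = 0.798), and their members went both ways. Adjusted over the list alone, the metalloproteinase inhibitor Timp2 was higher (3155 ± 241 and 6238 ± 1350 CPM), as was Mmp11 (11.1 ± 1.79 and 25.4 ± 2.52 CPM), while the plasminogen activator Plat was lower (75.1 ± 14.8 and 30.4 ± 5.40 CPM). Mmp3, or stromelysin, stood at 1790 ± 95.5 and 1139 ± 267 CPM (adjusted p = 0.607). Lining markers did not pass (9 tested, camera adjusted p = 0.961), and with adjustment over the list alone the protease Htra1 was higher (127 ± 24.6 and 232 ± 32.4 CPM) and the growth factor Hbegf lower (23 ± 2.72 and 11.4 ± 4.18 CPM).

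Genes of hypoxia and glycolysis were shifted downward, with 24 of 33 tested members negative and a median of -0.30 (camera adjusted p = 0.000846, adjusted p = 0.119 with an estimated correlation). No member passed over all genes in edgeR, DESeq2 or limma-voom or over the list alone, and 8 lay under an unadjusted 0.05 in edgeR, 6 lower and 2 higher with compound 33. The lower ones included the glycolytic enzymes Pgam1 (log2 fold change -0.80, SE 0.24) and Ldha (-0.56, SE 0.25), the kinase Pdk1 (-0.79, SE 0.26) and the mitophagy receptor Bnip3 (-0.54, SE 0.19). The higher ones were Egln3 (0.60, SE 0.24), a prolyl hydroxylase that HIF induces, and Ndrg1 (0.77, SE 0.35). Subunits of oxidative phosphorylation did not pass in all 6 libraries (47 tested, median -0.10, camera adjusted p = 0.0575), and passed downward without DMSO replicate 3 (adjusted p = 0.0415), without compound 33 replicate 2 (0.0211), in DESeq2 (0.0375) and in limma-voom (0.0319). Cell-cycle genes did not pass (53 tested, median -0.02, camera adjusted p = 0.963), and passed upward without compound 33 replicate 3 (adjusted p = 0.00457). Genes of cholesterol synthesis (adjusted p = 0.512), fatty acid metabolism (0.961), p53 signalling (0.665), cytosolic heat shock (0.80) and ribosomal proteins (0.961) did not pass at camera. Of the 10 lists that passed, fry passed those of the integrated stress response, inflammatory mediators, NRF2, the aryl hydrocarbon receptor and hypoxia (adjusted p = 0.0443 each), while its adjusted p was 0.163 for the interferon and contractile lists. Median, mean and test differed in sign for the lists of matrix degradation, p53 signalling, cell cycle and ribosomal proteins, none of which passed.

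**Figure D2:**
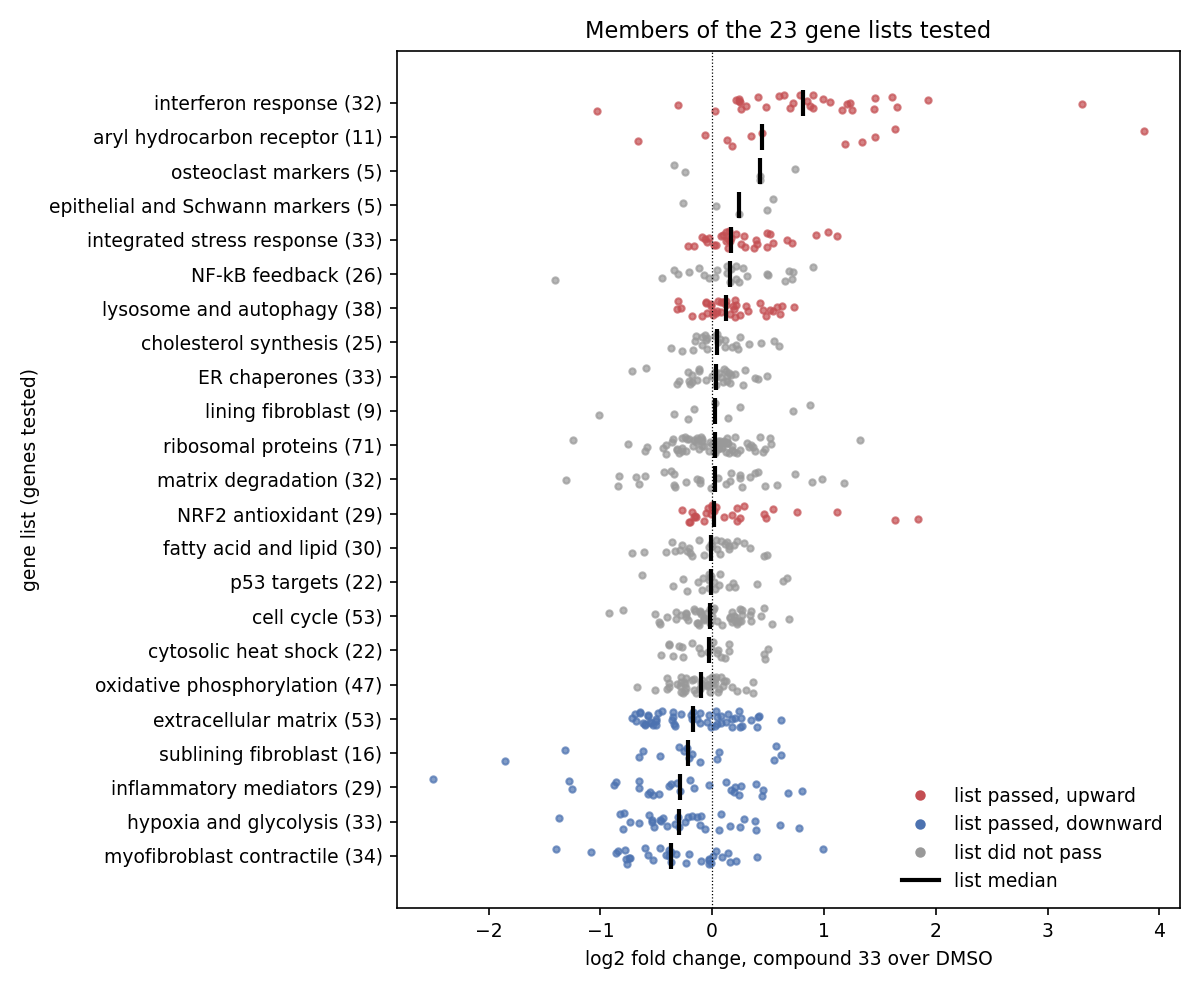
Log2 fold change of compound 33 over DMSO for each tested member of the 23 lists, 1 point per gene, with a black bar at the list's median and the number of tested genes in brackets. Red lists passed upward and blue lists downward at camera with a preset correlation, 5 each, and with an estimated correlation 0 lists passed; medians run from 0.82 for the interferon list to -0.37 for the contractile list.

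The cultures carried the transcripts of fibroblasts in both groups. Vim stood at 2271 ± 336 CPM with DMSO and 2641 ± 268 CPM with compound 33, Pdpn at 3767 ± 1816 and 3244 ± 767 CPM, Pdgfra at 144 ± 31.7 and 123 ± 39.5 CPM, Cdh11 at 144 ± 35.5 and 111 ± 19.5 CPM, and the lubricin gene Prg4 at 222 ± 72.8 and 245 ± 59.5 CPM. None of these passed. The most abundant genes included S100a6 (10534 ± 2459 and 16080.0 ± 227 CPM), the tetraspanin Cd63 (8768 ± 672 and 9872 ± 1833 CPM) and Gm42674 (11086 ± 1848 and 11351 ± 1832 CPM), a gene model that shares exons with S100a4 and S100a3 on the same strand, so that its reads cannot be assigned with certainty. Markers of other cell types were mostly under the counting filter. Of 24 macrophage markers 4 were tested, of 18 lymphocyte and neutrophil markers 3, of 16 endothelial markers 2, of 10 mural markers 3, of 17 cartilage and bone markers 4, of 12 adipocyte markers 3 and of 15 skeletal muscle markers 1, which was too few for the list test. Adjusted over each of those lists alone, the mural markers Cspg4 (higher) and Acta2 (lower) and the adipocyte marker Cebpa (higher) passed. The macrophage gene Lyz2 stood at 60.4 ± 38.2 and 50.8 ± 19.3 CPM, and Cd14 at 25.9 ± 11.2 and 18.3 ± 3.01 CPM. Lists of 5 tested osteoclast markers (camera adjusted p = 0.486) and 5 tested epithelial and Schwann cell markers (camera adjusted p = 0.320) did not pass, and 0 of 13 mitochondrial genes were in the table.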

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

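No list that passed, in the fit reported or under an alternative, changed direction in its test, and RLE, upper-quartile and total-count scaling, edgeR without robust estimation and the stricter filter each passed the same 3 genes. The count of genes moved from 1 upward and 2 downward to 11 and 10 without a low-count filter, and to 9 and 9 with DESeq2, where a different test and 10063 genes with an adjusted p apply. Limma-voom passed 1 gene upward and 1 downward, and an adjusted p under 0.01 in edgeR left 1 downward; the cause was not tested beyond the stricter threshold itself. Leaving out 1 library in turn gave 1 to 3 genes upward and 0 to 4 downward, with fewer samples in each fit. The extremes were 7 genes in all without DMSO replicate 1 and 1 without DMSO replicate 3 or compound 33 replicate 1. Of the lists, 5 upward and 5 downward became 0 and 0 with an estimated correlation between genes and 3 and 2 with fry. That estimate ran up to 0.35 for the interferon list, but lay under the preset 0.01 for the inflammatory (-0.0085) and NRF2 (-0.017) lists. For the latter lists a higher correlation between members cannot be the reason, and the reason was not tested. When 1 library was left out, 4 to 6 lists passed upward and 3 to 6 downward, the 3 downward without DMSO replicate 2 or compound 33 replicate 1. The log2 fold change of Hyou1 ran from -0.093 to 0.47 over those fits, turning negative without DMSO replicate 2. Other genes near 0 turned sign there too, Gm42674 from -0.048 to 0.18, Lyz2 from -0.61 to 0.40, Pdgfra from -0.39 to 0.022, Pdpn from -0.43 to 0.25 and Prg4 from -0.093 to 0.36, and the cause was not tested. The authors' deposited table and edgeR shared 3 genes at an adjusted p under 0.05 and 2 under 0.01. The replicate numbers were not taken to pair the samples, by a rule fixed beforehand that asked for a correlation over 0.1 for every number. With 3 pairs this cannot exclude a pairing, and the labels leave it open. Deviations of same-numbered libraries from their group means correlated across genes at -0.03 to 0.21, under 0.1 for 2 of 3 numbers, and 3 of 6 libraries correlated best with their own number. With the replicate block, 4 genes passed upward and 3 downward, namely the 3 that passed without it and Car6, Ifit3, Rsad2 and Il6, and the same 10 lists passed. Depth limits the lowest levels that could be seen, 1.04 to 1.83 CPM per library for a gene with 0 reads. In simulated data with 3 libraries per group edgeR recovered 30.8% of 2-fold changes. Depth, spread, the number of libraries and the number of changed genes were not varied apart.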

Other observations

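The tests on NRF2 genes, leukocyte transcripts and cell-cycle genes were chosen only after the results they bear on had been seen. So was the use, with 1 library left out, of the whole aryl hydrocarbon receptor list and of all measured members of the contractile list. Several genes outside the fixed lists also differed in the authors' deposited table. Klf9, a transcription factor that steroid hormones induce, stood at 19.2 ± 7.22 CPM with DMSO and 70.8 ± 36.7 CPM with compound 33, and Car6, a secreted carbonic anhydrase, at 8.57 ± 5.12 and 31.4 ± 6.48 CPM (mean ± SD, n = 3). Chsy1, a chondroitin synthase, stood at 174 ± 8.45 and 93.3 ± 7.17 CPM, and Csrp2, a LIM-domain protein of the cytoskeleton, at 215 ± 45.6 and 96.0 ± 21.8 CPM. Cxcl3, a chemokine encoded like Ppbp on chromosome 5 (90786103 to 90789600), stood at 73.7 ± 11.6 and 30.0 ± 11.9 CPM. None of the 5 passed in edgeR over the 10124 genes tested, with an adjusted p of 0.266 for the first 4 and 0.294 for Cxcl3, and without a low-count filter all of them but Chsy1 passed in edgeR, Car6 also with the replicate block (adjusted p = 0.0478). Hif1a, which encodes the oxygen-regulated factor that drives glycolytic genes and was chosen after its values were seen, stood at 892 ± 150 and 503 ± 32.5 CPM (log2 fold change -0.83, edgeR adjusted p = 0.401).

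Ahrr, Cyp1b1, Nqo1, Tiparp and Aldh3a1, the targets of the aryl hydrocarbon receptor that passed when adjusted over their list alone, had a median log2 fold change of 1.46, against 0.45 for all 11 tested members of the list. Whether a general NRF2 response, which also induces Nqo1, plays a part stays open. NRF2 genes outside the receptor's list had a median of 0.012 (quartiles -0.09 to 0.26), below the 0.45 of the receptor's list. The whole NRF2 list, which includes Nqo1, nevertheless passed upward at camera (adjusted p = 0.00832) and fry (adjusted p = 0.0443). Of its 29 tested members 17 were positive, so the median alone cannot decide. Glucocorticoid receptor targets, written down before they were looked at, had a median of 0.20 (quartiles -0.28 to 0.40 over 10 tested genes), below the 0.5 set beforehand for this explanation, a bar that the list of the aryl hydrocarbon receptor does not reach, and with an upper quartile narrowly below that list's 0.45. Of these genes 7 were positive and 3 negative, and Klf9, which steroid hormones induce, was not among them. This explanation therefore stays open too. With 1 library left out the 5 genes had a median of 1.38 to 1.88, but they were picked because they passed, and the whole list had 0.33 to 0.64, so a part played by 1 library stays open. These values are consistent with the hypothesis that compound 33 or a product of it may activate the receptor in these cells, which was not tested by any measurement of binding.

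Interferon-stimulated genes were higher with compound 33, with a difference in mean log2 CPM of 0.75 between the groups. Leukocytes in the treated cultures are argued against only as carriers of the added reads. A set of 16 abundant leukocyte transcripts summed to 20.1 CPM with DMSO and 16.1 CPM with compound 33, a change of -0.448% of the summed rise of the list. H2-Ab1, the highest of them in both groups, stood at 5.18 CPM with DMSO and 3.87 CPM with compound 33. Of the 4 tested macrophage markers, Laptm5 and Ctss were higher with compound 33 and Lyz2 and Cd14 lower, and none passed. The sum cannot show whether a few leukocytes acted on the fibroblasts. A single library is not the whole cause, since the median log2 fold change of the list stayed at 0.52 or above, but compound 33 replicate 1 carries part of it, as that lowest value was reached without it. Variation between cultures cannot be told apart from an effect of the compound, because the list did not pass with an estimated correlation between genes (adjusted p = 0.147) or with fry (adjusted p = 0.163). Of the 10 splits of the libraries 1, the real one, reached 0.75 and the highest other reached 0.64. That other split set compound 33 replicates 1 and 3 with DMSO replicate 1, so it still holds part of the treatment difference. Whether the compound could raise interferon signalling stays open.

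Contractile genes were lower with compound 33, though their list did not pass with an estimated correlation (adjusted p = 0.200) or with fry (adjusted p = 0.163). A further set of 17 genes of serum response factor and the actin cytoskeleton, written down before their values were looked at, had a median log2 fold change of -0.31 (quartiles -0.35 to -0.10), with 14 negative. Leaving out 1 library kept the median of those 17 genes between -0.30 and -0.25. A different stage of growth stays open, since cell-cycle genes went both ways around a median of -0.017 (quartiles -0.16 to 0.22), and that list passed upward without compound 33 replicate 3 (median 0.21). Whether 1 library carries the contractile list is open, since without compound 33 replicate 1 its median was -0.22 over the 34 genes tested in all libraries and -0.17 over all members measured in that fit, on either side of the bound of -0.18 set beforehand. A general decline of actin-cytoskeleton transcripts may therefore underlie part of the list, a hypothesis found and tested on the same libraries.

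Splits of the 6 libraries cannot give a share under 0.05, since 3 against 3 make 10 of them. The real split gave 3 genes and 10 lists, each reached by 1 of the 10 splits, the real one. The highest other split for genes gave 1. Every other split also passed lists at camera with the preset correlation, from 1 to 6 of them. Each side of those splits mixed the groups unequally, so part of a treatment difference remained. The splits therefore show that lists pass for mixed groupings too, but not how often they pass without any treatment difference. Before adjustment the real split had 696 genes under 0.05, and 3 of the 9 other splits had more. These were the splits that group DMSO replicates 1 and 3 with compound 33 replicate 3 (866 genes), DMSO replicate 1 with compound 33 replicates 2 and 3 (840 genes) and DMSO replicate 1 with compound 33 replicates 1 and 3 (729 genes), so the libraries also differ in ways that their groups do not describe.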
